A study of Homo sapiens with 6 samples.

How the data were processed

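RNA was measured in D283, an established human medulloblastoma cell line. Per the labels' protocols, cultures were transduced with a GFP-marked lentivirus that carried a guide RNA against OTX2 or a non-targeting guide, with 3 infections of each kind, and cells were collected after 7 days. Total RNA was sequenced from the 6 cultures. The labels name the genotype of each library, which placed 3 libraries in the control group and 3 in the OTX2 knockout group. The number of guides, the source of the nuclease, the share of edited cells, the library kit and any batch or date are not given in the sources used here. The replicates are separate infections of 1 cell line, so p-values measure the spread between those infections.

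The authors deposited a table of unnormalized counts per gene, with 1 column per library and no pooled columns. STAR and the hg38 genome build are named per the submitters' processing notes. The version of STAR, the counting program, the gene annotation, the strand setting and any filter are not given in the sources used here. The table held 50883 gene symbols, of which 17682 had 0 counts in all 6 libraries, and 0 entries named no gene. Columns were assigned to libraries by title. Counts per library summed to between 54540645 and 62166870, and 3 counts corresponded to between 0.0483 and 0.0550 CPM, that is counts scaled to a common library size. Intervals and limits based on counts cover counting error only, because reads without molecular identifiers are not independent molecules.

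Strand-specific counting was not stated, so reads from overlapping genes could not be assigned with certainty. Symbols were matched to GENCODE release 29 on GRCh38, which supplied coordinates, transcript length and GC content for 15583 of 18420 tested genes (84.6%). A named gene is marked as uncertain where its exons overlap those of another gene holding over 10% of its count. Older symbols were looked up in RefSeq gene synonyms for GRCh38 patch 14.

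Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its default settings, libraries were scaled by the trimmed mean of M values (TMM), and the groups were compared with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest). P-values were adjusted over the 18420 tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Expression is given as CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries. Fold changes are ratios of mean CPM. Log2 fold changes come from the fit, with their standard error (SE), and no SE is given for a gene at 0 in a whole group. The fit had 4 residual degrees of freedom and a biological coefficient of variation of 5.30%.

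Gene lists were written from textbook knowledge of medulloblastoma, rhombic lip development, neuronal and retinal differentiation, growth, stress and other cell types. The 34 lists held 844 entries, 815 of which were in the count table, 20 of them through an older symbol. Lists with at least 5 tested genes, 33 in all, were tested with camera from limma 3.58.1, which compares the genes of a list with all other genes. The preset correlation between genes was 0.01, and p-values were adjusted over the lists by the Benjamini-Hochberg method. For each list the number of members past the gene test is given over all tested genes and adjusted over the list alone.

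The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took OTX2, then the 12 largest rises and the 12 largest falls in log2 fold change among genes with a symbol, and then up to 4 members of each tested list with the smallest adjusted p. The rises and falls required an adjusted p under 0.05, a mean count of at least 100 and no overlap between the CPM values of the groups. Clone names, annotated pseudogenes and genes that mark sex were left out. Some genes that the rule takes are left out of the text. Any other gene is named as chosen after its values were seen.

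The alternatives were other scalings (RLE size factors, upper-quartile factors and library totals alone), no filter, and a stricter filter of at least 1 CPM in at least 3 libraries. Further alternatives were leaving out each library in turn, DESeq2 1.42.0, limma-voom, removal of mitochondrial and rRNA genes, a test against a 1.5-fold change (glmTreat), and a threshold of 0.01. For the lists they were camera with an estimated correlation, camera on ranks and fry. A correction for GC content and length of the longest transcript with splines of 5 degrees of freedom, and a fit of protein-coding genes alone, were added after the data were seen.

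The scripts were tested on simulated data drawn from the control means, depths and fitted dispersions of these libraries, with 200 genes changed. For the comparison of OTX2 knockout with control, edgeR tested 17844 simulated genes. It recovered 45.7% of genes changed 1.2-fold, 80% of those changed 1.5-fold, 87.8% of those changed 2-fold and 100% of those changed 4-fold. Of 164 calls, 12 were false (7.32%). On 17827 simulated genes, camera called 1 of 1 list of 30 genes moved by 1.3-fold and 0 of 20 lists that had not moved. Simulated genes were drawn independently, so false list calls that arise from correlation between genes were not tested. The 200 changed genes were also far fewer than the 7312 called in the data, so scaling under so broad a change was not tested.

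Libraries of a group were compared before averaging. Over genes with at least 50 counts in a pair, every pair of libraries differed by more than sampling noise, with a chi-square per gene between 4.75 and 23.9 within groups, so each library counted as 1 replicate.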

Results

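The series comprised 6 total RNA libraries from D283, an established cell line derived from a medulloblastoma, a malignant tumour of the cerebellum. The labels place 3 libraries in a group that received a guide RNA against OTX2 and 3 in a group that received a non-targeting guide. OTX2 encodes a homeobox transcription factor of the developing brain and retina. The title of the series concerns the rhombic lip, the embryonic source of several cerebellar neurons, and Group 3 and Group 4 medulloblastoma. The comparison addresses which genes differ in expression when OTX2 is targeted in these cells. Total counts were 56315049, 61662466 and 54540645 in control replicates 1 to 3, and 61154088, 60561438 and 62166870 in knockout replicates 1 to 3.

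The groups separated on the leading principal component of log2 CPM, which carried 76.1% of the variance. Pearson's r across genes, which are not independent replicates, lay between 0.9954 and 0.9966 within groups and between 0.981 and 0.9833 across groups. Control replicate 1 stood apart from the other controls. Its mitochondrially encoded genes took 0.764% of counts, against 0.449% and 0.440% in the other controls and 0.531% to 0.601% in the knockout libraries. Its ribosomal RNA share was 0.305%, against 0.0971% and 0.0675% in the other controls and 0.0941% to 0.111% in the knockout libraries.

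OTX2 RNA fell slightly in the knockout group. Its mean level went from 964 ± 48.4 to 825 ± 61.1 CPM (SD, n = 3 per group), a log2 fold change of -0.22 (SE 0.06, adjusted p = 0.00646 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The control libraries held 1002, 979 and 909 CPM, and the knockout libraries 765, 824 and 887 CPM, so the groups did not overlap. OTX2 lies on the minus strand of chromosome 14, from 56799905 to 56810479 on GRCh38 in GENCODE release 29, where it is annotated as protein-coding. An edit can leave the transcript in place, so the RNA level is a weak check of the labels. The edited sequence was not analysed here.

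The knockout libraries differed from control in a large part of the transcriptome, and the large changes were mostly rises. Of 18420 genes tested, 7312 changed, 3908 of them upwards and 3404 downwards (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of more than 2-fold comprised 1113 rises and 144 falls. The balance of rises and falls depended on scaling: rises made up 53.4% of the changed genes with TMM and 71.9% with library totals alone, where 5210 genes rose and 2034 fell. With DESeq2, 3230 genes rose and 3345 fell. CPM values of the groups did not overlap for 9054 of the 18420 tested genes (49.2%), where chance gives 10%. Against a 1.5-fold change in place of no change, glmTreat called 1207 genes, and OTX2 was not among them.

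**Figure D1:**
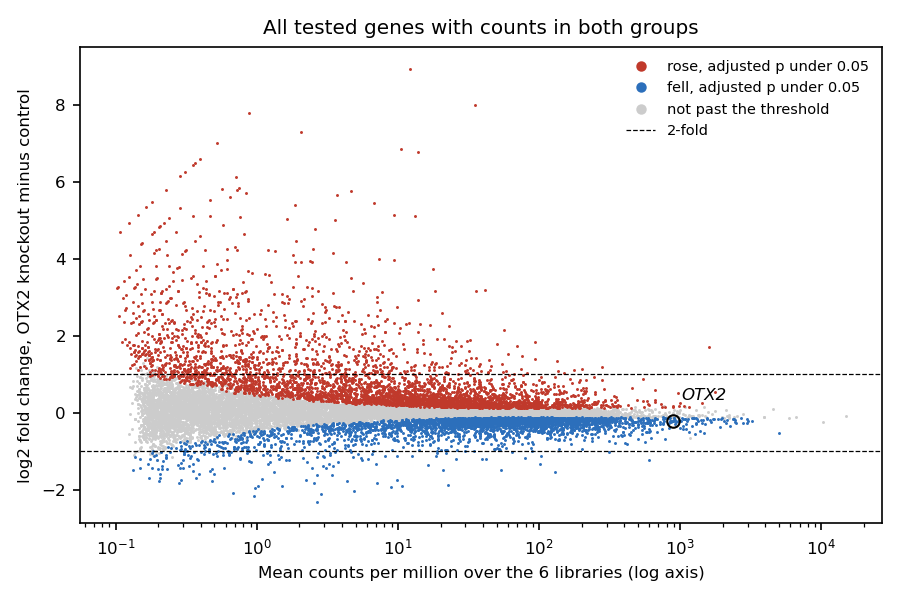
Log2 fold change (OTX2 knockout minus control) against mean CPM over 6 libraries on a log axis, for each tested gene with counts in both groups, leaving out 10 genes at 0 in a whole group. Red points rose and blue points fell at an adjusted p under 0.05, dashed lines mark 2-fold, more red than blue points lie beyond them (1113 rises and 144 falls over all tested genes), and the circle marks OTX2 at -0.22.

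The largest rises under the rule for named genes were in genes nearly silent in control cells. KRT15, a keratin of basal epithelium, rose from 0.274 ± 0.0658 to 70.2 ± 8.47 CPM (SD, n = 3 per group), a log2 fold change of 7.99 (SE 0.14). KRT5, another basal keratin, rose from 0.0237 ± 0.0277 to 4.06 ± 0.109 CPM. The KRT5 control level rests on 4 counts, and the 95% counting interval of its ratio runs from 66.2 to 627. MFNG, a glycosyltransferase that modifies Notch receptors, rose 116-fold, and NPTXR, a neuronal pentraxin receptor, rose 109-fold. The neurogenic transcription factor NHLH1 rose 55-fold, the muscle-type acetylcholine receptor subunit CHRNA1 51.7-fold, and the ephrin receptor EPHB2 43.8-fold. CACNA2D2, a calcium channel subunit, rose 35.4-fold, CABP7 34.5-fold, KIAA0319 33.5-fold and the interferon-induced IFI44L 32.1-fold. KIAA0319 had the largest adjusted p of these rises, 4.8e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Exons of CABP7 overlap ZMAT5, so its count is uncertain.

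The largest falls were smaller. IGFBP3, which binds insulin-like growth factors, fell from 4.43 ± 0.32 to 0.89 ± 0.274 CPM (SD, n = 3 per group), a log2 fold change of -2.31 (SE 0.16). TTR, the transthyretin made by choroid plexus and retinal pigment epithelium, fell 4.09-fold, and TRPM1, a cation channel of melanocytes and retinal bipolar cells, fell 3.8-fold. The nucleoside transporter SLC28A3 fell 3.76-fold and the serine protease PRSS56 3.67-fold. MAEL, a protein of the germline piRNA pathway, fell 3.37-fold, and PRDM1, a transcription factor that acts in photoreceptor precursors, fell 3.09-fold. At higher expression, AKAP5 fell from 192 ± 6.51 to 66.6 ± 6.27 CPM, complement C3 from 79.1 ± 5.58 to 27.9 ± 1.65 CPM, and the basement membrane collagen COL4A3 fell 2.82-fold. RAPGEF3 fell 3.51-fold and KIAA1257 3.37-fold, but their exons overlap SLC48A1 and ACAD9. MAEL had the largest adjusted p of these 12 genes, 4.7e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

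**Figure D2:**
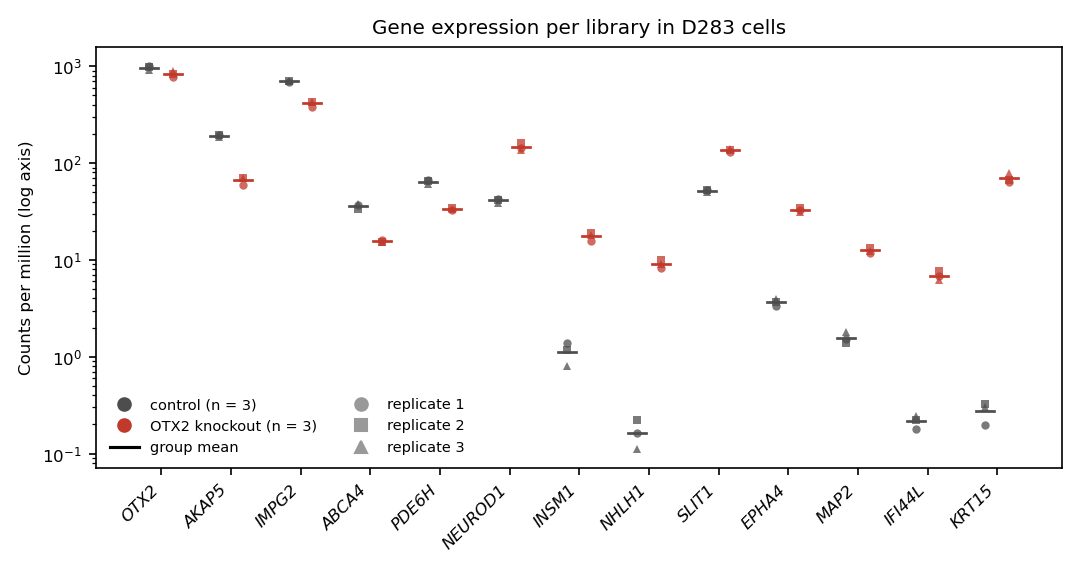
CPM of OTX2 and 12 further genes in each library on a log axis, with control in grey, knockout in red, marker shape for the replicate and a bar for the group mean (n = 3). Knockout means lie below control for OTX2, AKAP5, IMPG2, ABCA4 and PDE6H and above control for the other genes, with KRT15 going from 0.274 ± 0.0658 to 70.2 ± 8.47 CPM.

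Neuronal differentiation genes rose as a group. Of 22 tested neurogenic and neural transcription factors, 20 rose and 0 fell, with a median log2 fold change of 0.99 (camera adjusted p = 1.01e-25). NEUROD1 rose from 41.2 ± 2.24 to 147 ± 13.6 CPM, INSM1 15.7-fold and MYT1 8.72-fold. Of 32 tested pan-neuronal genes, 25 rose and 4 fell (median 1.2, camera adjusted p = 2.20e-24), and the sodium channel SCN3A rose 15.2-fold, the microtubule protein MAP2 7.99-fold, SYT4 4.85-fold and CHGA 4.2-fold. ELAVL4, chosen after its values were seen, had 0 counts in the controls and 251 in the knockout libraries, at least 74.3-fold higher against a floor of 3 counts over the control group, and the pan-neuronal median was the same with ELAVL4 at that bound. Of 51 tested axon guidance genes, 29 rose and 10 fell (median 0.27, camera adjusted p = 1.65e-13). EPHA4 rose 8.93-fold, SEMA6A 8.94-fold and SLIT1 from 51.9 ± 0.914 to 135 ± 4.26 CPM, and exons of SEMA6A overlap CTB-118N6.3. Adjusted over the list alone, 21 transcription factors rose and 0 fell, 26 and 4 for the pan-neuronal genes, and 29 and 10 for axon guidance. With library totals alone 2 pan-neuronal and 5 axon guidance genes fell, and without knockout replicate 2 there were 6 falling axon guidance genes.

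Most tested genes in the lists of rhombic lip derivatives rose. In the granule neuron lineage list, 18 of 22 tested genes rose and 2 fell (median 1.0, camera adjusted p = 3.05e-16; adjusted p = 0.063 with an estimated correlation), led by NHLH1, INSM1, NEUROD2 (10.3-fold up) and NEUROD1. The falling genes, named after their values were seen, were CNTN1 and GABRA6, and 1 gene fell without control replicate 2, control replicate 3 or knockout replicate 1. NHLH1, INSM1 and NEUROD1 are also in the neurogenic transcription factor list, so the calls of these lists are not independent. In the list of the rhombic lip subventricular zone and unipolar brush cells, 11 of 15 rose, and the 1 that fell was OTX2 itself (median 0.57, camera adjusted p = 3.46e-05; adjusted p = 0.0518 with an estimated correlation). FOXP2 rose 2.88-fold, LHX9 3.81-fold and PLCB4 8.77-fold. The median was the same with SLN, chosen after its values were seen and at 0 counts in the controls and 87 in the knockout libraries, at its bound of at least 25.8-fold higher against 3 counts over the control group. EOMES, a transcription factor of unipolar brush cells chosen after its values were seen, was at 0.238 ± 0.0139 CPM in control and 0.275 ± 0.0884 CPM in knockout, with an adjusted p of 0.653 by edgeR's quasi-likelihood test. The counts adjusted over the list alone were 19 up and 2 down for granule neurons, and 11 and 1 for the subventricular zone.

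Of 11 tested genes of the rhombic lip ventricular zone, 3 rose and 6 fell, and the list did not pass (camera adjusted p = 0.313), with a median of -0.13, a mean of 0.11 and a camera direction of down. SLC1A3 fell 1.66-fold, NOTCH2 from 706 ± 41.4 to 510.1 ± 17.8 CPM and MSX1 1.39-fold, while the progenitor filament NES rose 1.56-fold. With library totals alone, 3 of these genes fell. The list of CBFA complex genes and Group 4 drivers did not pass (camera adjusted p = 0.222), with 4 of 11 tested genes up and 2 down, 1 of them down with library totals alone. The corepressor CBFA2T2 rose from 51.8 ± 4.07 to 83 ± 2.21 CPM and RUNX1T1 1.72-fold. MYCN rose from 0.431 ± 0.127 to 1.7 ± 0.258 CPM, with exons that overlap MYCNOS, and SNCAIP fell 1.26-fold. Counts adjusted over the list alone were 4 up and 6 down for the ventricular zone and 5 and 2 for the CBFA list. Fry, which does not compare a list with other genes, called the ventricular zone list (adjusted p = 0.0223) and the CBFA list (0.00834).

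Some genes listed for the sonic hedgehog (SHH) pathway rose. Of 9 tested, 5 rose and 0 fell, with the same counts adjusted over the list alone (median 0.18, camera adjusted p = 0.000898; adjusted p = 0.0777 with an estimated correlation). BOC rose 3.43-fold, with exons that overlap WDR52, and SFRP1 rose 1.63-fold. The direct targets GLI1 and PTCH1, chosen after their values were seen, had log2 fold changes of -0.16 and 0.13, with adjusted p values of 0.204 and 0.266 by edgeR's quasi-likelihood test. On ranks, camera did not call the list (adjusted p = 0.052), and without knockout replicate 1 there was 1 falling gene.

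Photoreceptor genes fell together. Of 32 tested, 24 fell and 1 rose, with a median log2 fold change of -0.9 (camera adjusted p = 1.09e-12; adjusted p = 0.0777 with an estimated correlation), and the same counts held adjusted over the list alone. The transporter ABCA4 fell from 36.2 ± 2.07 to 15.6 ± 0.408 CPM, the cone phosphodiesterase subunit PDE6H from 64.1 ± 2.49 to 33.5 ± 0.642 CPM, and the interphotoreceptor matrix protein IMPG2 from 702 ± 9.7 to 413 ± 26.7 CPM. GNB3 fell 2.2-fold, with exons that overlap CDCA3. Among genes chosen after their values were seen, the rod determinant NRL fell from 28.9 ± 2.23 to 14.6 ± 0.944 CPM, and CRX from 273 ± 10 to 241 ± 17.7 CPM, a log2 fold change of -0.18 (SE 0.06). The member that rose, also named afterwards, was NEUROD4, a proneural factor (8.46-fold up). In the photoreceptor list 2 genes rose without control replicate 1, 2 or 3, or without knockout replicate 3.

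Growth-related lists and the integrated stress response list fell by small amounts. Of 38 tested MYC targets, 33 fell and 0 rose (median -0.23, camera adjusted p = 1.20e-07; adjusted p = 0.157 with an estimated correlation), and CAD fell 1.31-fold, DKC1 1.31-fold, BOP1 1.37-fold and the chaperonin HSPD1 1.27-fold. MYC itself, a member chosen after its values were seen, fell from 1725 ± 118 to 1204 ± 159 CPM. Of 26 tested genes of the integrated stress response, 20 fell and 3 rose (median -0.28, camera adjusted p = 0.000424; adjusted p = 0.485 with an estimated correlation). TRIB3 fell 1.4-fold, ASNS 1.55-fold, PSAT1 1.4-fold and CEBPB 1.36-fold. The rising members, named after their values were seen, were ATF3, HSPA5 and DNAJB9. Of 43 tested cytosolic ribosomal protein genes, 25 fell and 0 rose (median -0.14, camera adjusted p = 0.000748; adjusted p = 0.719 with an estimated correlation), among them RPL13 (1.2-fold down), RPS2 (1.17-fold down) and RPL3 (1.17-fold down), genes whose counts can share reads with pseudogenes. Adjusted over the list alone, 34 MYC targets, 21 stress genes and 32 ribosomal protein genes fell, and 4 stress genes rose. The number of falling ribosomal protein genes was 8 with library totals alone, 8 and 14 without control replicates 2 and 3, and 10 and 13 without knockout replicates 1 and 2. With library totals alone, and without knockout replicate 1, 13 stress genes fell. The number of falling MYC targets was 25 with library totals alone.

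Cell cycle lists sat close to the threshold. Of 33 tested G1/S genes, 10 fell and 1 rose (median -0.11, camera adjusted p = 0.034; adjusted p = 0.745 with an estimated correlation), and of 36 tested G2/M genes, 10 fell and 1 rose (median -0.1, camera adjusted p = 0.0368; adjusted p = 0.745 with an estimated correlation). CDCA7 fell 1.33-fold, CDT1 1.28-fold and TPX2 from 463 ± 9.14 to 352 ± 12.9 CPM, while the cyclin CCNE1 rose 1.24-fold. ECT2 fell 1.22-fold and CDC20 1.18-fold. Counts adjusted over the list alone were 9 down and 1 up for G1/S, and 10 down and 1 up for G2/M. The G1/S call was lost with library totals alone (adjusted p = 0.0741, 4 down and 3 up), and without control replicate 2 (0.0637, 5 down), control replicate 3 (0.0753) or knockout replicate 3 (0.118, 3 up), and the G2/M call was lost with library totals alone (0.106, 5 down and 5 up), and without control replicate 2 (0.0637) or knockout replicate 1 (0.117, 6 down). Both calls were also lost with the stricter filter (0.0792 for G1/S and 0.0860 for G2/M), with fry (0.122 and 0.0613) and after the GC and length correction (0.0581 and 0.106). Without control replicate 1, the library with more mitochondrial and ribosomal RNA, 19 G1/S and 16 G2/M genes fell.

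Interferon-induced and antigen presentation genes rose. Of 20 tested interferon response genes, 12 rose and 0 fell (median 0.98, camera adjusted p = 2.45e-06), and all 7 tested genes of MHC class I presentation rose (median 1.19, camera adjusted p = 0.000185; adjusted p = 0.0777 with an estimated correlation). IFIT1 rose 2.76-fold, DDX60 3.81-fold and IFI44 2.2-fold. TAPBP rose 1.61-fold, B2M from 84 ± 2.63 to 112 ± 1.95 CPM and HLA-E 2.44-fold, where HLA genes are similar in sequence and their counts are uncertain. The counts adjusted over the list alone were again 12 and 7. Of 11 immune cell markers, 4 reached the test, and CD14 rose and CSF1R fell (both named after their values were seen), with 0 markers up without control replicate 1, control replicate 2 or any of the knockout replicates.

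Markers of other lineages rose as well. Of 26 tested mesenchymal and extracellular matrix genes, 18 rose and 4 fell (median 0.81, camera adjusted p = 4.99e-06), with the collagen COL1A2 up 9.49-fold, TNC 7.71-fold, SNAI2 2.2-fold and COL1A1 2.1-fold. Their median was the same with POSTN, chosen after its values were seen and at 0 counts in the controls and 44 in the knockout libraries, at its bound of at least 13-fold higher against 3 counts over the control group. Of 9 tested muscle genes, 8 rose and 0 fell (median 0.8, camera adjusted p = 1.41e-07; adjusted p = 0.0777 with an estimated correlation), including the troponin TNNI1 (15.3-fold up), CKM (2.44-fold up) and DES (2.69-fold up), which overlaps AC053503.4. Of 7 tested astroglial markers, 4 rose and 0 fell (median 0.98, camera adjusted p = 1.14e-05; adjusted p = 0.0777 with an estimated correlation), with the apolipoprotein APOE up 2.91-fold, SPARCL1 1.98-fold, GJA1 from 154 ± 12.7 to 279 ± 23.8 CPM and AGT 4.16-fold. Adjusted over the list alone, 18 mesenchymal genes rose and 4 fell, 8 and 0 for muscle, and 5 and 0 for the astroglial markers.

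In all, 17 of 33 tested lists passed the camera threshold, 11 upwards and 6 downwards. With an estimated correlation 5 calls held, all upwards: neurogenic transcription factors (adjusted p = 0.0301), axon guidance (0.0301), pan-neuronal genes (0.0375), interferon response (0.0375) and mesenchymal genes (0.0375). In each of the 9 other splits of the libraries into 3 and 3, camera with the preset correlation called 12 to 17 lists, and with an estimated correlation 0. Those splits mix control and knockout libraries, so they are not free of the group difference. The medians of these 17 lists kept their sign with RLE factors, upper-quartile factors and library totals.

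**Figure D3:**
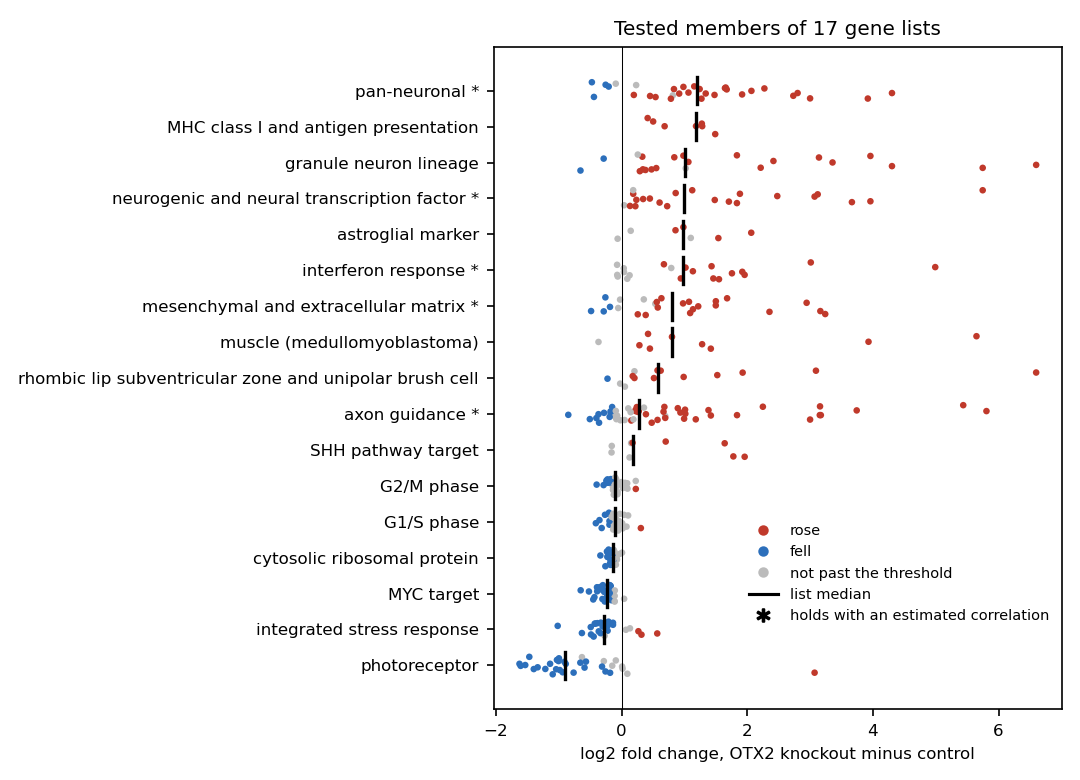
Log2 fold change (OTX2 knockout minus control) of the tested members of 17 gene lists, 1 point per gene with counts in both groups, coloured by the gene test, with the list median as a bar and an asterisk on the 5 lists whose call held with an estimated correlation. The medians run from -0.9 for photoreceptor genes to 1.2 for pan-neuronal genes.

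Lists of p53, Wnt, Notch, BMP and apoptosis genes did not pass with camera, although some of their members changed. Fry, which does not compare a list with other genes, called each of these lists. Its adjusted p was 0.0055 for p53, 0.0042 for Wnt, 0.0145 for Notch, 0.0189 for BMP and 0.0285 for apoptosis. Of 25 tested p53 targets, 8 rose and 7 fell (camera adjusted p = 0.181), the cell cycle inhibitor CDKN1A rising from 170.3 ± 17.4 to 388 ± 31.6 CPM, BTG2 2.3-fold and TP53INP1 2.16-fold, and 3 fell with library totals alone or without control replicate 2. Of 10 tested Wnt targets, 5 rose and 2 fell (camera adjusted p = 0.404), NKD1 rising 2.53-fold and FZD7 falling 1.68-fold, and 3 rose without control replicate 2. Of 14 tested Notch genes, 5 rose and 3 fell (camera adjusted p = 0.553), HEY1 rising 2.38-fold and JAG2 falling 1.45-fold. The Notch median was -0.01, its mean 0.36 and its camera direction up, and the median was above 0 with upper-quartile factors (0.0085), library totals (0.07), and without control replicate 2 (0.017), control replicate 3 (0.0049) or knockout replicate 2 (0.0097). Of 18 tested BMP and TGF-beta targets, 8 rose and 3 fell (camera adjusted p = 0.213, and 0.04995 with no filter), with ID2 up 2.22-fold, ID4 2.14-fold and SMAD7 3.03-fold. Of 20 tested apoptosis regulators, 8 rose and 5 fell (camera adjusted p = 0.485), HRK rising 2.6-fold, and 5 rose without knockout replicate 2. Counts adjusted over the list alone were 9 up and 7 down for p53, 6 and 2 for Wnt, 5 and 3 for Notch, 8 and 3 for BMP, and 9 and 5 for apoptosis.

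Metabolic and remaining lists did not pass either. Of 26 tested hypoxia and glycolysis genes, 2 rose and 7 fell (camera adjusted p = 0.192), HK1 rising 2.05-fold and the glucose transporter SLC2A1 falling 1.64-fold. Without knockout replicate 3, 18 of them fell (adjusted p = 2.02e-05), and camera on ranks gave 0.0265. Of 13 tested mitochondrially encoded genes, 6 rose and 0 fell (camera adjusted p = 0.192), with 12 up without control replicate 1 (adjusted p = 1.96e-05) and 3 up without control replicate 2, control replicate 3 or knockout replicate 1. Camera called them with no filter (adjusted p = 0.030) and on ranks (0.00566). Of 24 tested cholesterol synthesis genes, 7 rose and 1 fell (camera adjusted p = 0.493), 4 of them up without knockout replicate 1 or 2, and 0 or 2 down with library totals or RLE factors. Counts adjusted over the list alone were 2 up and 7 down, 6 and 0, and 7 and 1 for these lists.

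Homeobox and PAX factors (15 tested, 5 up and 1 down) had a camera adjusted p of 0.553, with 3 and 2 down without control replicate 3 and knockout replicate 2. HOX genes (8 tested, 1 up and 1 down) had 0.944, with 0 up without control replicate 2, control replicate 3, knockout replicate 1 or knockout replicate 2, and 2 up without knockout replicate 3 or with upper-quartile factors or library totals. Neural crest and melanocyte genes (7 tested, 2 up and 2 down) had 0.544, DCT falling 1.47-fold. Oligodendroglial markers (5 tested, 2 up and 1 down) had 0.485, OLIG2 rising 3.47-fold. Endothelial and mural markers (7 tested, 2 up and 3 down) had 0.097, and 0.0438 with the stricter filter, RGS5 falling 2.19-fold and VWF rising 1.84-fold, with 1 up without control replicate 2 or knockout replicate 1. Histone genes (15 tested, 1 up and 0 down) had 0.357, a median of -0.1, a mean of 0.0058 and a camera direction of down, with 8 down without control replicate 1, 4 down without knockout replicate 3, 2 down with RLE factors, and 0 up without control replicate 1, control replicate 2 or knockout replicate 1. Counts adjusted over the list alone were 5 and 1, 0 and 1, 3 and 2, 2 and 1, 2 and 3, and 0 and 0 in the same order. Fry called the homeobox (adjusted p = 0.0342), neural crest (0.00433), oligodendroglial (0.0254) and endothelial (0.0064) lists, but not the HOX (0.0705) or histone (0.467) lists.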

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

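The correction for GC content and transcript length and the fit of protein-coding genes alone were chosen only after the results were seen. The number of changed genes stayed within 1.5 times of 7312 in all but 1 alternative: 7389 with RLE factors, 7215 with upper-quartile factors, 7244 with library totals, 7576 with no filter, 6420 with the stricter filter, 6575 with DESeq2 (6294 shared with edgeR), 7312 with limma-voom (7222 shared), 7320 without mitochondrial and rRNA genes, 5184 at an adjusted p under 0.01, 7882 after the GC and length correction and 6566 among protein-coding genes. Leaving out 1 library at a time gave 5897 to 7514. The exception was glmTreat with 1207, which tests against a 1.5-fold change by construction. The balance of rises and falls turned in 2 alternatives: 53.4% of the changed genes rose with edgeR, 49.1% with DESeq2 and 44.1% after the GC and length correction, and the cause was not tested.

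The log2 fold change of OTX2 lay between -0.29 and -0.17 as each library was left out and reached -0.15 with library totals, with adjusted p values from 0.000137 to 0.0426 over the alternatives, except glmTreat, which did not call it against a 1.5-fold change (adjusted p = 1). Called lists numbered 15 to 19 over scalings, filters, ranks and the GC and length correction, and 15 to 18 as each library was left out. With an estimated correlation camera called 5 lists, and fry, which does not compare a list with other genes, called 26. Over all alternatives and lists, 449 verdicts were unchanged, 26 calls were lost and 18 were gained. For named genes other than OTX2, 2269 were unchanged, 16 calls were lost and 22 were gained.

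No paired analysis was possible because the titles number the libraries 1 to 6, with no number shared between the groups. Depth limits genes near 3 counts per library, and 10 tested genes had 0 counts in a whole group.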

Other observations

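The gene lists of the opening paragraphs, and the tests of unedited cells, a single wrong label, edits that leave the RNA in place, immune cells, the count floor in control and the GC and length correction, were chosen only after the results they bear on were seen. Genes named here were likewise chosen after their values were seen. The lists below are given without the genes that the rule for named genes had taken. Genes of retinal pigment epithelium and choroid plexus fell: of 16 tested, 10 fell and 0 rose (median -0.34, camera adjusted p = 0.0169, and 5.45e-06 with the named genes included; adjusted p = 0.442 with an estimated correlation). The channel TRPM3 fell from 402 ± 26 to 266 ± 3.82 CPM, SERPINF1 1.42-fold and the visual cycle isomerase RPE65 from 24 ± 2.54 to 14.6 ± 3.27 CPM.

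Other lists of this kind did not pass. Of 12 tested germline and piRNA pathway genes, 4 fell and 1 rose (camera adjusted p = 0.197, and 0.0368 with MAEL), with TDRD9 down 2.7-fold. Of 24 tested sodium and calcium channel genes, 14 rose and 6 fell (camera adjusted p = 0.0879, and 5.45e-06 with CACNA2D2 and SCN3A), with SCN3B up 3.78-fold and CACNA2D3 down 1.97-fold. Of 36 tested neurotransmitter receptor genes, 16 rose and 7 fell (camera adjusted p = 0.227, and 0.0249 with the named genes included), with GRIA2 up 5.36-fold and GABRA5 down from 159 ± 2.86 to 99.9 ± 4.69 CPM. For complement, 5 of 14 rose and 2 fell (camera adjusted p = 0.712), for NF-kB targets 6 of 10 rose and 1 fell (0.197), and for the MYC family 3 of 9 rose and 1 fell (0.712).

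Hypoxia genes differed between the knockout libraries. Against the control mean, the list median was -0.27, -0.26 and 0.08 on the log2 scale in knockout replicates 1 to 3. BNIP3 stood at 71.0, 77.4 and 209 CPM and NDRG1 at 27.2, 31.2 and 78.2 CPM in those libraries.

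OTX2 RNA fell little in libraries labelled as knockout. If edited cells had lost the RNA and unedited cells had kept it, the unedited cells would be the large majority, and no gene lowered in edited cells alone could fall by much more than OTX2, yet 31 genes with a mean count of at least 100 had a 95% interval below -1 on the log2 scale. A single library with the other group's label is argued against by 0 of 6 libraries that correlated better with the other group, which would not reveal an exchange of the whole groups. Edits that break the reading frame and leave the RNA in place may account for the change of -0.22, but this stays open, since the edited sequence was not analysed here.

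Rises of more than 2-fold outnumbered falls by a ratio of 7.73. The excess did not depend on the choice among RLE, upper-quartile and library-total scaling, with a lowest ratio of 7.12. The median log2 fold change of all genes ran only from -0.0031 to 0.085 over these scalings, so a larger scaling error was not tested. GC content or transcript length is argued against by a ratio of 8.17 after correction. For genes near the count floor, which cannot fall far, the planned test gave 5.4 at a mean CPM over the 6 libraries of at least 10 (108 rises and 20 falls), but silent control genes enter that set through their rise. A test on control level, put in its place afterwards, gave 4.04 at a control mean CPM of at least 1 (319 rises and 79 falls). The ratio was 2.54 at 10 or more (66 and 26) and 0.667 at 100 or more (4 and 6). Rises thus still outnumbered falls at 1 or more and at 10 or more. The floor could account for part of the excess and stays open. Basal epithelial cells are a possible source of KRT15 and KRT5. They are argued against by 7 of 8 other markers that did not rise or lay under 10% of the KRT5 level (KRT14 at 0.0318 CPM in knockout). The exception was KRT17 at 39.6% of the KRT5 level. Only 3 of the 8 reached the test. KRT17 and SFN rose (SFN from 0.101 to 0.228 CPM), and PERP, at 218% of the KRT5 level, did not. The other markers could not be called as rising, so for them the argument rests on their low level alone.

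Interferon response and MHC class I genes rose, 19 of 27 in the joined lists, with 0 that fell. A general rise of weakly expressed genes is argued against, since their median of 1.02 was at percentile 100 of 10000 random lists matched on mean expression, the highest of which reached 0.47, and 0.57 when matched on control level alone, a matching added afterwards. Immune cells are argued against by 1 of 11 markers that rose (CD14, 0.175 CPM in knockout), though only 4 markers reached the test, and PTPRC was at 0.217 CPM. Heavier lentiviral exposure of the knockout cultures may also account for the median of 1.02 and cannot be told apart from the group, since vector sequence was not analysed here. Loss of OTX2 itself stays open as well, as untested.

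Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 7312 changed genes and the highest of the others 0 by edgeR, with 8730 and between 82 and 537 at an unadjusted p under 0.05, so that 1 of 10 splits gave as many. For the gene lists 2 of 10 splits gave as many, since the real split called 17 with the preset correlation and the others 12 to 17. The number of preset-correlation calls therefore does not set the groups apart. With an estimated correlation the real split called 5 lists and each of the others 0. Each of the other splits joins 2 libraries of 1 group with 1 of the other. Part of the group difference stays in such a split and part widens its spread. Neither their 12 to 17 calls nor their 0 calls can therefore decide which list calls are false. Loss of chromosome 14 material beyond OTX2 in a large share of the cells was argued against. The median log2 fold change of 250 genes beyond OTX2 was -0.05, that of 175 genes before it was -0.03, and the difference was -0.019. The median beyond OTX2 lay at percentile 3.9 of random lists, with 71 genes down and 50 up, against 44 down and 41 up before OTX2. Loss in a small share of the cells would move the median little and stays open.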
